A study of Arabidopsis thaliana with 7 samples.

How the data were processed

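Small RNA libraries from inflorescences labelled wild type (1 library), rdr2 (2) and dcl2,3,4 (2) and PARE libraries labelled wild type and xrn4 were taken from the series. The deposited small RNA files hold 1 raw sequencing read per line with its base qualities, and the reads were sequenced by Illumina per the labels. The authors' deposited lists give, for each distinct small RNA or 20-nt PARE signature, a count of genome matches (hits), pooled over libraries, with neither abundance nor genotype. Their matching tool and genome build are not given in the sources used here.

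The 3' adapter was removed where its first 6 bases (TCGTAT) occurred, with the last occurrence taken, and inserts of 18 to 28 nt without ambiguous bases were kept. This kept 79.0% of reads in the library labelled wild type, 75.0% and 82.0% in those labelled rdr2 and 77.7% and 79.8% in those labelled dcl2,3,4. Reads were 32 or 33 nt long, so inserts above 26 or 27 nt were not seen. Distinct sequences were matched exactly to both strands of the TAIR10.1 assembly, nuclear and organelle, and 71.5 to 79.7% of trimmed reads matched. Of the trimmed distinct sequences, 99.4% were in the authors' list, and for 98.9% of those the number of matches equalled theirs. Sequences matching annotated rRNA, tRNA, snRNA or snoRNA genes in sense were left out, and the remaining matched reads gave the library size. PCR duplicates could not be recognised, so intervals and floors cover counting error only. A floor is 3 counts.

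Counts were made for exact sequences, for annotated loci (either strand, each read at every locus it matches, so near-identical and overlapping genes share reads), and for 24-nt reads with 1 genomic position in 1 kb windows. Features needed 20 reads over the 5 libraries. The count test planned beforehand, which was meant also for counts made from reads, was not run, because it was kept for deposited count tables and the files hold none. Instead limma-voom (limma 3.58.1, R 4.3.3) was fitted to all 5 libraries with the library sizes above, moderated by eBayes, with Benjamini-Hochberg adjustment at 0.05. The spread came from the mutant pairs, with 2 residual degrees of freedom. Libraries of 1 label differed beyond sampling noise (chi-square per degree of freedom 8.82 for rdr2 and 7.67 for dcl2,3,4), so they were kept apart. Fixed lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists within a comparison. The agreement of comparisons sharing wild type was simulated 10 times with a dispersion of 0.02.

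Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data with 200 changed features. For the libraries labelled rdr2 against wild type, over 7105 loci, 22% of 100 loci changed 2-fold and 65% of 100 changed 4-fold were called, with 2 false calls. The shares were 3% and 21% over 3792 windows and 1% and 13% over 19718 sequences. The site search recovered 200 of 200 planted sites, and the search for inverted repeats 50 of 50 planted repeats.

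PARE sites were found by ungapped placement of each listed miRNA on the annotated transcripts of its listed targets (mismatch 1, G:U 0.5, doubled at miRNA nucleotides 2 to 13, maximum 5), before signatures were consulted. Bulged sites are missed. A signature counted as present if its 20 nt began at the position opposite miRNA nucleotides 10 and 11. For each miRNA 100 shuffled copies were searched in the same way.

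Features named in the text follow a rule fixed before the data were examined: all TAS loci, the 4 most abundant members of each fixed list, the mutated genes, and the 4 loci with the largest change in each direction among those past the threshold, with a mean of at least 20 RPM and 1 direction in every mutant library. The rule for PARE genes needed abundances and could not be applied, so families were described instead. SDC, the remaining members of each list and loci with fewer than 20 reads were tested only in counts. Alternatives fixed beforehand covered the scaling (TMM and median-of-ratios factors, both computed from their published definitions in own code, and library size by listed miRNA reads), the read filter, each mutant replicate left out, the replicate number as a block, isoforms, unique matches and window size. Added after seeing the data were limma-trend, fits on the compared libraries only, mutant libraries summed by run, and 1 mismatch in the adapter.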

Results

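Small RNAs were sequenced from whole inflorescences of Arabidopsis thaliana in 5 libraries: 1 labelled wild type (Col-0), 2 labelled rdr2 and 2 labelled dcl2,3,4. RDR2 is an RNA-dependent RNA polymerase that makes double-stranded precursors of 24-nt small interfering RNAs (siRNAs), and DCL2, DCL3 and DCL4 are Dicer-like enzymes that process such precursors. The design also holds 2 PARE libraries, labelled wild type and xrn4. PARE (parallel analysis of RNA ends) records the 5' ends of uncapped polyadenylated RNA, and XRN4 is a cytoplasmic 5' to 3' exoribonuclease. For PARE, only a list of distinct signatures without abundance or genotype was analysed here.

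Raw reads numbered 1816216 in the library labelled wild type, 2889955 and 2947183 in those labelled rdr2, and 2923262 and 2535390 in those labelled dcl2,3,4. After adapter removal and exact matching to the genome, 984035, 1559757, 1708757, 1642633 and 1368615 reads outside structural RNA remained, in the same order. These totals served as library sizes. Read names placed both mutant libraries numbered 1 in one sequencing run, both numbered 2 in another, and the wild-type library on a further instrument, so the run and wild type cannot be told apart. The labels do not say whether libraries of a genotype came from separate plants, so p-values measure the spread between libraries, which may be technical. Wild type had no replicate and was assumed to vary like the mutants.

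Small RNA reads at the mutated genes were too few to check the labels, and reads of 18 to 28 nt do not measure the mRNA. RDR2 (AT4G11130) held 0 reads in wild type, 1 and 3 in the libraries labelled rdr2, and 2 and 0 in those labelled dcl2,3,4. DCL2 (AT3G03300) held 0, 2, 3, 0 and 3 reads in that order, and DCL4 (AT5G20320) held 1, 2, 5, 3 and 6. DCL3 (AT3G43920) held 0 reads in wild type and 11, 13, 9 and 4 in the 4 mutant libraries, at most 2.50-fold over a floor of 3 wild-type reads. Its adjusted p was 0.011 for rdr2 and 0.043 for dcl2,3,4, and the call ended with features of at least 5 reads, with reads of 1 genomic position and with library size by listed miRNA reads. XRN4 (AT1G54490) held 1, 1, 5, 4 and 1 reads. The libraries labelled rdr2 and dcl2,3,4 were nearly alike in every measure below, although different small RNA losses are known for these genotypes. Each is therefore called the library labelled with its genotype.

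The 24-nt class was the most abundant in the library labelled wild type and was largely lost in all 4 mutant libraries. It made up 46.5% of reads in wild type (95% exact binomial interval 46.4 to 46.6%). It made up 2.93% and 3.20% in the libraries labelled rdr2, and 2.93% and 3.18% in those labelled dcl2,3,4. The wild-type share was 15.2 times the mean of the 4 mutant libraries. The 21-nt class made up 24.6% in wild type and 62.6%, 61.9%, 63.0% and 61.5% in the mutant libraries, and the 20-nt class 4.47% and 18.2%, 16.9%, 17.7% and 17.6%. The 23-nt class made up 13.3% in wild type and between 4.15% and 4.64% in the mutants. No test across groups was made on these shares, and intervals cover counting error only. Fragments of rRNA took 3.11% of genome-matched reads in wild type and 6.70 to 7.19% in the mutant libraries, and tRNA fragments took 0.969% and 2.22 to 3.45%.

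**Figure D1:**
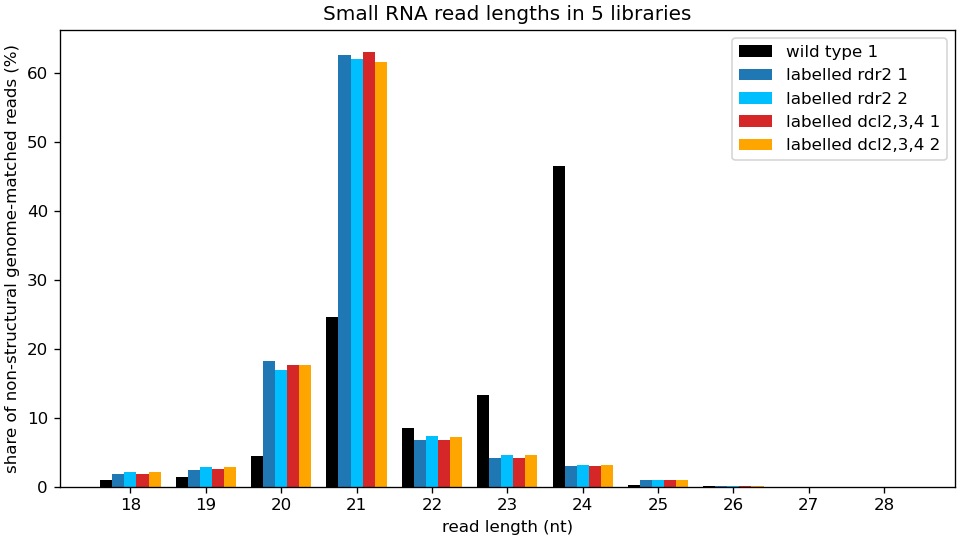
Share of non-structural genome-matched reads (%, y axis) at each read length (nt, x axis), with 1 bar per library. The 24-nt bar stands at 46.5% in the library labelled wild type and at 2.93 to 3.20% in the 4 mutant libraries.

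The first comparison asked which small RNAs change without RDR2, if the label is right. Its changes describe libraries with this label, which is weighed under the other observations. In the libraries labelled rdr2, 24-nt siRNAs fell across the genome, 30 of 55 listed miRNAs took a larger share of reads, and trans-acting siRNA loci (TAS genes, whose transcripts are cut by a miRNA and diced into 21-nt siRNAs) moved in both directions. For 24-nt siRNA windows rdr2 vs wild type, 3530 of 3792 windows of 1 kb were lower and 12 higher (limma-voom, Benjamini-Hochberg adjusted p under 0.05), with a median log2 change of -4.64. For annotated loci rdr2 vs wild type, 3780 of 7105 loci were lower and 422 higher, with a median of -0.95. With TMM factors, which set the median locus near 0 (0.0073), 1034 loci were lower and 1039 higher, and 249 windows were lower and 80 higher. With median-of-ratios factors 1059 loci were lower and 1000 higher, and 307 windows were lower and 77 higher. The median window change was -0.26 and -0.41 with these factors. With library size by listed miRNA reads the median was -2.25 for loci and -5.94 for windows.

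Of 55 listed miRNAs measured, 30 were higher and 5 lower in the libraries labelled rdr2, and 35 also passed when adjusted over the list alone. Among 32 conserved miRNAs, 18 rose and 4 fell. miR156a, which targets SPL transcription factor mRNAs, rose by 2.13 (SE 0.10) on the log2 scale, from 8681 to 39172 and 36918 RPM (reads scaled to a common library size). miR172a, which targets AP2-type mRNAs, rose by 1.57 (SE 0.09) and miR166a, which targets HD-ZIP III mRNAs, by 1.79 (SE 0.15). miR167a, the most abundant listed miRNA in wild type, had a log2 change of 0.29 (SE 0.13, adjusted p = 0.084), negative with the 3 other scalings. It passed when 1 library was left out (miR167a rdr2 vs wild type without rdr2 replicate 2, 0.42, adjusted p = 0.0072) and with the sequencing run as a block (0.29), but not with the mutant libraries of both labels summed by run (0.29, adjusted p = 0.071). Among 21 miRNAs of the Arabidopsis lineage, 12 rose and none fell. miR158a rose by 2.78, miR391 by 2.21 and miR173, the trigger of TAS1 and TAS2, by 1.46. miR161.2 rose from 676 to 3043 and 2418 RPM. The conserved and lineage lists did not pass camera (adjusted p = 0.096 and 0.065). Both passed fry upward (adjusted p = 0.026 each), which tests whether a list moves on balance one way, does not compare it with other features, and was run with the main scaling only. The 5 that fell were miR839, miR160a (-1.27), miR169d (-1.05), miR169h (-1.86) and miR398b (-2.68), the last 4 named after their values were seen.

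The rises of miRNAs are shares of a library that lost its 24-nt class, and the split depends on the scaling. Listed miRNAs made up 16.5% of reads in wild type, 42.3% and 38.9% in the libraries labelled rdr2 and 42.0% and 38.9% in those labelled dcl2,3,4. The median log2 change of all sequences in the libraries labelled rdr2 was 1.75, against 0.71 with TMM factors, 0.39 with median-of-ratios factors and 0.45 with library size by listed miRNA reads. With these scalings 18, 6 and 9 listed miRNAs were higher and 11, 15 and 13 lower. The call of miR173 ended with each of these scalings, that of miR172a with the last 2, and those of miR166a and miR161.2 with median-of-ratios factors. The call of miR158a ended when features needed only 5 reads. miR839, a miRNA known to depend on DCL4, fell by 3.33 (SE 0.34, adjusted p = 4.6e-05), from 88.4 to 9.62 and 7.61 RPM. miR822, also known to depend on DCL4, had a log2 change of 0.39 (adjusted p = 0.18). This list of 2 did not pass camera (adjusted p = 0.11) and passed fry downward (adjusted p = 0.027).

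Of 7 TAS loci measured in the libraries labelled rdr2, 3 rose and 3 fell. TAS1B (chromosome 1, 18549204 to 18550042) fell by 1.35 (SE 0.13, adjusted p = 4.2e-09), TAS2 (chromosome 2, 16539384 to 16540417) changed by -0.52 and TAS1A (chromosome 2, 11721539 to 11722468) by -0.45. TAS1C (chromosome 2, 16537288 to 16538277) rose by 0.52, TAS3B (chromosome 5, 20134200 to 20134786) by 0.83 and TAS3A (chromosome 3, 5861491 to 5862437) by 0.34. TAS3C had a log2 change of 0.39 (adjusted p = 0.31), and TAS4 held 2 reads of 21 nt in wild type and 1 or 0 in each mutant library. The list's median was 0.34 and its mean -0.03, so they differ in sign, and it passed neither camera (upward, adjusted p = 0.096) nor fry (downward, adjusted p = 0.19). The sign of TAS1A and TAS2 flipped with TMM and median-of-ratios factors, and that of TAS1C, TAS3A, TAS3B and TAS3C with library size by listed miRNA reads. Without rdr2 replicate 1 the call of TAS3A rdr2 vs wild type ended (0.32, adjusted p = 0.052). The siRNA tasiARF, made from TAS3, fell by 1.49 (SE 0.17) in its exact sequence.

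Of 16 protein-coding genes known to yield phased siRNAs, 7 rose and none fell in the libraries labelled rdr2. AT1G62930, AT1G63130 and AT1G63150 rose by 0.47, 0.34 and 0.33, and AT1G62910 had a log2 change of 0.18 (adjusted p = 0.20). With the run as a block AT1G62910 rdr2 vs wild type passed (0.18, adjusted p = 0.0065), but not on run sums (0.14, adjusted p = 0.40). The list passed camera with its preset correlation (adjusted p = 3.6e-07), but adjusted p = 0.35 with an estimated correlation and 0.23 by fry. All 4 changed sign with library size by listed miRNA reads, and AT1G62930 and AT1G63150 also with reads of 1 genomic position. Without rdr2 replicate 2 the calls of AT1G63130 rdr2 vs wild type (0.28, adjusted p = 0.098) and AT1G63150 rdr2 vs wild type (0.23, adjusted p = 0.18) ended, the latter also without dcl2,3,4 replicate 1 (0.33, adjusted p = 0.054), on run sums (0.28, adjusted p = 0.094), with limma-trend (adjusted p = 0.053) and with the compared libraries only (adjusted p = 0.060). Of 5 loci listed for RNA-directed DNA methylation, 4 fell. FWA fell by 3.61 (SE 0.65), from 21 reads to 3 and 2, the retroelement AtGP1 (AT4G03650) changed by -1.19 and the transposon AtMU1 (AT4G08680) by -0.80, although the sign of AtMU1 flipped with TMM and median-of-ratios factors and the call of AtGP1 ended with both. ROS1, a DNA demethylase gene that is not silenced by this pathway but known to depend on it for expression, had a log2 change of 0.01 (adjusted p = 0.98). This list had camera adjusted p = 0.32 and passed fry downward (adjusted p = 0.026).

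The locus of MIR839A (chromosome 1, 25278944 to 25279207) rose by 1.36 while the exact miR839 fell, and MIR822A and MIR869A had log2 changes of 0.16 and 0.76 (adjusted p = 0.42 and 0.15). The 3 DCL4-dependent MIR genes passed camera (adjusted p = 0.0069) and fry upward (adjusted p = 0.031), but adjusted p = 0.35 with an estimated correlation. Of 4 housekeeping genes, EF1A and UBQ10 rose by 1.08 and 1.67, while GAPC1 and ACT2 had 1.42 and 0.19 (adjusted p = 0.083 and 0.85). Of 2 leaf photosynthesis genes, RBCS1A rose by 1.15 and LHCB1.3 had 0.64 (adjusted p = 0.080). These lists had camera adjusted p = 0.0090 and 0.039, each with adjusted p = 0.35 with an estimated correlation, and fry adjusted p = 0.12 and 0.25. Of the loci that rose, EF1A and RBCS1A changed sign with library size by listed miRNA reads, and EF1A also with reads of 1 genomic position. The former moved the median locus from -0.95 to -2.25. That shift also makes the changes of MIR822A, MIR869A, LHCB1.3 and ACT2 negative. The calls of UBQ10 and MIR839A ended with library size by listed miRNA reads, and that of UBQ10 also with reads of 1 genomic position. Without rdr2 replicate 2 the call of RBCS1A rdr2 vs wild type ended (0.83, adjusted p = 0.053), and without rdr2 replicate 1 LHCB1.3 rdr2 vs wild type passed (0.88, adjusted p = 0.014), as it did with the run as a block (0.63, adjusted p = 0.027) and with limma-trend (adjusted p = 0.049), but not on run sums (0.64, adjusted p = 0.053). GAPC1 rdr2 vs wild type passed on run sums (1.32, adjusted p = 0.048) and with limma-trend (adjusted p = 0.017). Adjusted over the list alone, each locus list kept its count of calls. Floral organ, tapetum and the other pollen genes held at most 5 reads in any library. Reads at the pollen gene PPME1 fell by 2.55 (SE 0.25), from 115 reads to 36 and 29.

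Among loci with a mean of at least 20 RPM, the largest rises in the libraries labelled rdr2 were at AT1G76550, MIR319a, MIR5641 and MIR1887. AT1G76550 (chromosome 1, 28722657 to 28727111) held 0 reads in wild type and 75 and 91 in the libraries labelled rdr2, at least 15.8-fold and 17.5-fold higher against a floor of 3 wild-type reads. MIR319a (chromosome 4, 12352956 to 12353131) rose by 5.87 (SE 0.15), from 229.7 to 13026 and 13968 RPM. MIR5641 went from 1 read to 51 and 46, and MIR1887 from 2 to 68 and 76. The largest falls were at AT1G49260, AT1G13760, AT2G16575 and AT3G15960. AT1G49260 (chromosome 1, 18225870 to 18226967) went from 2314 reads to 3 and 2. AT1G13760 went from 663 reads to 1 and 0, AT2G16575 from 138 to 0 and 2, and AT3G15960 from 140 to 1 and 1.

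The second comparison asked which small RNAs change without DCL2, DCL3 and DCL4. In the libraries labelled dcl2,3,4, 24-nt siRNAs also fell across the genome, and the TAS loci again moved in both directions. The siRNAs of TAS loci depend on DCL4, and these libraries still held them, at a level relative to wild type that depends on the scaling. Their presence argues against the label, as weighed under the other observations. The changes in this comparison therefore describe libraries with this label. They are not read as effects of losing DCL2, DCL3 and DCL4. For 24-nt siRNA windows dcl2,3,4 vs wild type, 3529 of 3792 were lower and 11 higher, with a median log2 change of -4.56. Without replicate 2 of this label the count of changed windows was 2272. For annotated loci dcl2,3,4 vs wild type, 3734 of 7105 were lower and 383 higher, with a median of -0.92. With TMM factors 994 loci were lower and 943 higher, and 207 windows were lower and 73 higher. With median-of-ratios factors 1023 loci were lower and 913 higher, and 263 windows were lower and 69 higher. Of the 55 listed miRNAs, 30 were higher and 6 lower, and 36 passed when adjusted over the list alone. With TMM factors, median-of-ratios factors and library size by listed miRNA reads, 18, 6 and 8 were higher and 13, 17 and 14 lower.

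Among conserved miRNAs 18 rose and 5 fell in the libraries labelled dcl2,3,4, and among lineage miRNAs 12 rose and none fell (camera adjusted p = 0.11 and 0.066, fry adjusted p = 0.023 each, upward). miR156a rose by 2.12, miR172a by 1.60, miR166a by 1.72 and miR158a by 2.81. miR391, miR161.2 and miR173 rose by 2.11, 1.95 and 1.39. The calls of miR173, miR172a, miR166a, miR161.2 and miR158a ended with the settings named for the first comparison. miR167a had a log2 change of 0.28 (adjusted p = 0.093). It passed when either library labelled rdr2 was left out (miR167a dcl2,3,4 vs wild type, 0.28, adjusted p = 0.039 and 0.040), without dcl2,3,4 replicate 2 (0.43, adjusted p = 0.035) and with the run as a block (0.28), but not on run sums (0.29, adjusted p = 0.071). The 6 that fell were miR839, miR160a, miR169d, miR169h, miR398b and miR408, the last 5 named after their values were seen. miR839 fell by 4.06 (SE 0.40) and miR822 had a log2 change of 0.14 (adjusted p = 0.64), with camera adjusted p = 0.077 and fry adjusted p = 0.023, downward, for the DCL4-dependent miRNAs. TAS1B was 2.45 times lower (log2 SE 0.13), and TAS2 and TAS1A changed by -0.58 and -0.52. TAS1C rose by 0.50, TAS3B by 0.82 and TAS3A by 0.26, and TAS3C had a log2 change of 0.38 (adjusted p = 0.33). The call of TAS3A dcl2,3,4 vs wild type ended whichever mutant library was left out (0.26 to 0.27, adjusted p = 0.061 to 0.12), with limma-trend (adjusted p = 0.054) and with the compared libraries only (adjusted p = 0.066). The TAS list had a median of 0.26, a mean of -0.06, camera adjusted p = 0.12 (upward) and fry adjusted p = 0.096 (downward). The signs of TAS loci flipped with the scalings named for the first comparison. tasiARF fell by 1.62.

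Of the 16 phased siRNA genes, 7 rose and none fell in the libraries labelled dcl2,3,4, among them AT1G62930 by 0.40 and AT1G63130 by 0.36. AT1G63150 and AT1G62910 had log2 changes of 0.23 and 0.10 (adjusted p = 0.12 and 0.47). With the run as a block AT1G63150 dcl2,3,4 vs wild type passed (0.23, adjusted p = 0.00093), but not on run sums (0.28, adjusted p = 0.094). All 4 changed sign with library size by listed miRNA reads, and AT1G62930 also with reads of 1 genomic position. Without dcl2,3,4 replicate 2 the calls of AT1G62930 dcl2,3,4 vs wild type (0.32, adjusted p = 0.10) and AT1G63130 dcl2,3,4 vs wild type (0.28, adjusted p = 0.14) ended. The list had camera adjusted p = 1.9e-06, but adjusted p = 0.33 with an estimated correlation and 0.24 by fry. Of the 5 RNA-directed DNA methylation loci, 3 fell: FWA (-3.10), AtGP1 (-1.12) and AtMU1 (-0.66), the last with a flipped sign under TMM and median-of-ratios factors (camera adjusted p = 0.36, fry adjusted p = 0.023, downward). The call of AtGP1 ended with both, and ROS1 had a log2 change of -0.17 (adjusted p = 0.62). MIR839A rose by 1.46, UBQ10 by 1.61, EF1A by 0.83 and RBCS1A by 1.22, and the last 2 changed sign with library size by listed miRNA reads, EF1A also with reads of 1 genomic position. MIR822A and MIR869A had log2 changes of -0.02 and 0.50 (adjusted p = 0.92 and 0.36), LHCB1.3 0.64 (0.082), and GAPC1 and ACT2 1.23 and 0.27 (0.14 and 0.79). Library size by listed miRNA reads moved the median locus from -0.92 to -2.22, which also makes rises such as those of MIR869A, LHCB1.3 and ACT2 negative. The calls of UBQ10 and MIR839A ended as in the first comparison, and that of AtMU1 with reads of 1 genomic position. The call of EF1A dcl2,3,4 vs wild type ended whichever mutant library was left out (0.82 to 0.84, adjusted p = 0.058 to 0.080) and with the compared libraries only (adjusted p = 0.054), that of DCL3 dcl2,3,4 vs wild type without dcl2,3,4 replicate 1 (adjusted p = 0.055), and without the same library LHCB1.3 dcl2,3,4 vs wild type passed (0.93, adjusted p = 0.020), as it did with the run as a block (0.66, adjusted p = 0.021) and with limma-trend (adjusted p = 0.041), but not on run sums (0.64, adjusted p = 0.053). GAPC1 dcl2,3,4 vs wild type passed on run sums (1.32, adjusted p = 0.048) and with limma-trend (adjusted p = 0.032). Adjusted over the list alone, 1 of the 2 housekeeping calls held, and the other locus lists kept their counts. DCL4-dependent MIR genes and housekeeping genes each had camera adjusted p = 0.015 and leaf genes 0.033, all with adjusted p = 0.33 with an estimated correlation. By fry these 3 lists had adjusted p = 0.037, 0.13 and 0.24. PPME1 fell by 2.66.

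The largest rises in the libraries labelled dcl2,3,4 were at AT1G76550, with 73 and 78 reads (at least 14.6-fold and 18.7-fold higher), MIR319a with 5.83 on the log2 scale, MIR5641 with 46 and 48 reads and MIR1887 with 71 and 57. The largest falls were at AT1G49260, from 2314 reads to 1 and 2, AT1G13760, from 663 to 3 and 3, AT4G24974, from 165 to 1 and 2, and AT2G16575, from 138 to 1 and 3. Both comparisons used the same wild-type library. Across loci, which are not independent replicates, their log2 changes had r = 0.953 and a covariance of 1.93, against 0.747 and 0.305 for simulated unchanged groups sharing 1 control. Calls shared by both comparisons numbered 342 higher and 3492 lower, against 22.7 and 1987 for independent lists and 0 in the simulation. The simulation held no changed feature, so its 0 says little. Libraries of both labels were also nearly alike within a run, which by itself makes the lists coincide. Part of the excess may come from the shared control, which could not be split.

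The third comparison set the libraries labelled dcl2,3,4 against those labelled rdr2. Without the sequencing run in the fit, limma-voom called 0 of 55 listed miRNAs, also when adjusted over the list alone, 0 of 7105 loci and 0 of 3792 windows. At an unadjusted p under 0.05 there were 0 miRNAs, 201 for annotated loci dcl2,3,4 vs rdr2 and 168 for 24-nt siRNA windows dcl2,3,4 vs rdr2, and limma-trend also called 0 in each. Libraries of the same number shared a run and differed less (chi-square per degree of freedom 1.34 and 2.19) than libraries of different runs (7.67 to 8.82). With the run as a block, 3 of 7105 loci, 4 of 19718 sequences (2 of them listed miRNAs) and 0 windows were called, and 5 listed miRNAs when adjusted over the list alone. The loci were AT3G08845, AT3G08855 and AT5G60120, higher in the libraries labelled dcl2,3,4 by 1.72 (SE 0.26), 1.75 (SE 0.26) and 1.60 (SE 0.24), with adjusted p of at most 1.7e-07. The miRNAs were miR166a (adjusted p = 3.2e-05) and miR157a (adjusted p = 0.0042), with log2 differences of -0.060 and -0.057. From rdr2 to dcl2,3,4, miR166a went from 34348 to 35841 RPM in one run and from 33380 to 28538 in the other. Its 2 pairs thus disagreed in direction, while miR157a was lower in both. The block fit had fewer residual degrees of freedom, and its SE for miR166a was 0.010 against 0.094 without the run. Its p-values therefore do not measure the spread of single features. Of the 2 unlisted sequences, AGAATCCTGATGATGCTGCAT was higher in the libraries labelled dcl2,3,4 by 1.72 (SE 0.28, adjusted p = 2.1e-05). It differs from miR172a at 1 base and lay on the minus strand of chromosome 3, 21132663 to 21132683, inside AT3G08845 and AT3G08855, and of chromosome 5, 24210889 to 24210909, inside AT5G60120 (TOE2, an AP2-type gene among the listed miR172 targets). It had 16 and 28 reads in the libraries labelled rdr2 and 22 and 107 in those labelled dcl2,3,4. The last library held 112, 112 and 114 reads at the 3 loci, so these calls rest on 1 sequence and mostly on 1 library. That library held 56940 reads of miR172a, and whether the sequence is a misread of miR172a was not tested. AGACAAAAGCAGACGCAGCTCCA (plus strand of chromosome 2, 4107054 to 4107076 and 4108574 to 4108596) had 3 and 6 reads against 0 and 0 (adjusted p = 0.042), and 16 in wild type. These features were named after their values were seen. In the fit without the run, TAS loci differed by -0.08 (SE 0.08, TAS3A) to 0.05 (SE 0.12, TAS1B), and miR156a, miR172a and miR158a by -0.01, 0.02 and 0.03 (SE 0.06, 0.06 and 0.07). miR839 differed by -0.73 (SE 0.42). None of the lists passed camera, fry or camera with an estimated correlation in that fit. In simulated data for this comparison, without a run effect, 40% of loci changed 2-fold and 82% of those changed 4-fold were called. The shares were 22% and 60% for windows and 8% and 45% for sequences. Among features with at least 100 reads, 58.1% of loci, 57.1% of windows and 58.3% of sequences changed 2-fold were called, from 62, 21 and 12 such features, so 2-fold differences would mostly have been missed at features with fewer reads.

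At the 2867 windows with at least 20 wild-type 24-nt reads and away from MIR, TAS and structural genes, 24-nt reads with 1 genomic position went from 262623 RPM in wild type to 9065 and 9625 in the libraries labelled rdr2 and 9243 and 9791 in those labelled dcl2,3,4. At the same windows 21-nt reads went from 26782 to 144111, 149319, 146153 and 152521 RPM. Relative to listed miRNA reads, the summed 21-nt reads were 2.10 times wild type (95% interval over resampled loci 1.96 to 2.24) in the library labelled rdr2 with the lowest value and 2.41 times (2.25 to 2.57) in the library labelled dcl2,3,4 with the highest. Of the listed miRNA reads, miR167a alone held 90742 of 162247 in wild type and 192135 of 659273 in rdr2 replicate 1. Without miR167a these fold changes would be lower, and the interval does not cover this. This window set was chosen after the data were examined.

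**Figure D2:**
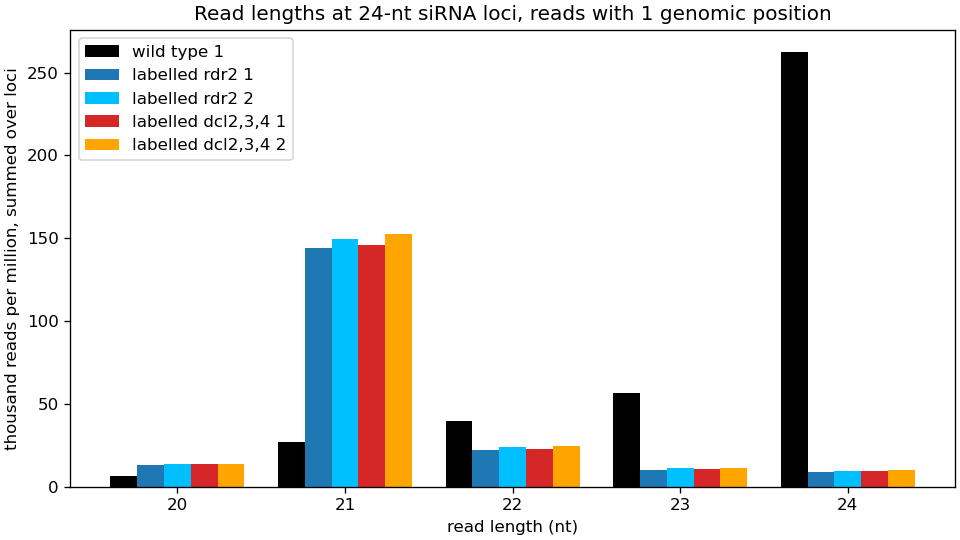
RPM in units of 1000 (y axis) by read length (nt, x axis), summed over 2867 windows with 24-nt siRNAs, with 1 bar per library. At 24 nt the library labelled wild type stands highest, and at 21 nt all 4 mutant libraries stand above it.

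PARE signatures were found at the expected cleavage position in 97 of 119 sites searched in listed targets, and signatures with 1 genomic match in 83. The pooled list held 7109274 distinct 20-nt signatures, of which 4882453 had a genome match in the authors' count. Of 131 pairs of a miRNA or tasiRNA and a target, 119 had an ungapped site within the maximum penalty. A signature began opposite miRNA nucleotides 10 and 11 at 97 of them (81.5%, 95% exact binomial interval 73.4 to 88.0%). Positions within 50 nt held a signature in 12.5% of cases. Shuffled miRNAs gave 15 sites in 100 copies, and none had a signature, too few for a background share. The comparison of xrn4 with wild type could not be made from the pooled list, and presence says nothing of abundance.

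By family, all 11 SPL sites of miR156, all 6 NAC sites of miR164, all 7 NF-YA sites of miR169, all 6 AP2-type sites of miR172, all 5 TCP sites of miR319 and all 5 sites of miR393 in auxin receptor genes and a bHLH gene held the expected signature, although 3 of the 11 and 1 of the 6 AP2-type sites rested on signatures with more than 1 genomic match. So did the 4 miR173 sites in TAS1 and TAS2 transcripts and the tasiARF sites in ARF2, ARF3 and ARF4. The 13 sites in 3' UTRs all held it (exact interval 75.3 to 100%), as did 74 of 94 in coding sequence. In AP2 (AT4G36920) the site lay in exon 11, chromosome 4, 17403019 to 17403039, with the 5' end at 17403030. miR159 had a signature at 2 of 8 MYB sites, MYB33 and MYB65, but it was the same sequence (TCATTCCAATATTCAGAAAC) with 2 genome matches, so it cannot be assigned to either gene, and 0 of the 8 held a signature with 1 match. miR408 had signatures at 1 of 4 sites. No ungapped site within the penalty was found for miR396 in 7 GRF genes or for miR162 in DCL1.

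**Figure D3:**
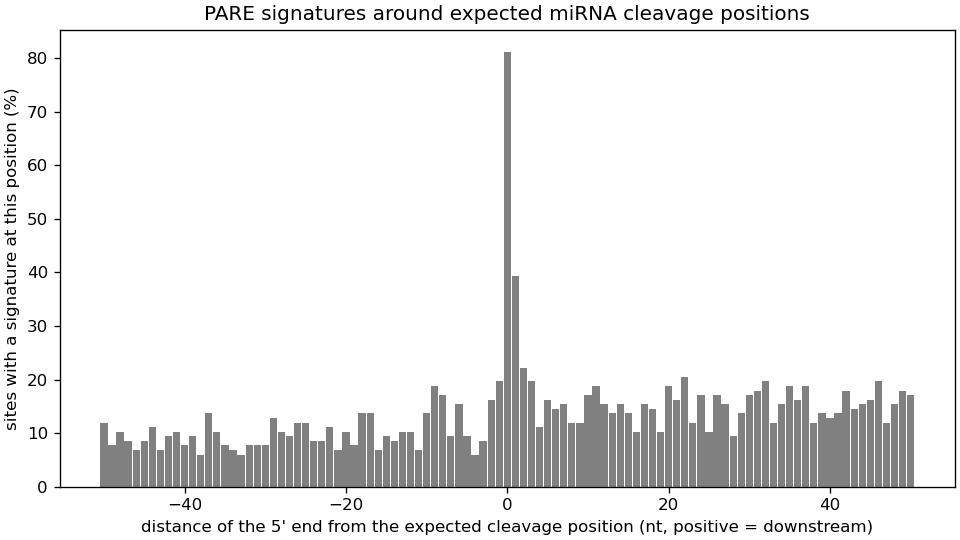
Share of expected cleavage sites with a signature (%, y axis) by distance of its 5' end from the expected position (nt, x axis), pooled over both PARE libraries. The share peaks at distance 0, above the 12.5% found on average at positions within 50 nt.

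Signatures covered 57.1% of transcript positions of PI, 45.6% of AP3, 33.3% of SEP3, 32.6% of AP1 and 17.2% of AG, all floral organ identity genes. They covered 28.6% of PPME1 and 26.4% of VGD1, pollen genes, 18.5% of A9 and 8.32% of AMS, tapetum genes, and 80.5% of LHCB1.3 and 67.9% of RBCS1A, leaf genes. The median over 27440 protein-coding genes was 5.50%. XRN4 was covered at 12.6% and RDR2 at 1.05%.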

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

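Alternatives named here as limma-trend, compared libraries only, mutant libraries summed by run and 1 mismatch in the adapter were chosen after seeing the data. Of 139 alternative values of summary results, 107 stayed within their limits and 32 moved. The 24-nt share stayed lower in the mutants and more called windows were lower than higher under each alternative run, while the direction of single miRNAs and TAS loci followed the scaling. The cause was not tested, unless fewer or more features entered the fit. Depth limits the comparisons most at loci with few reads and by the 1 wild-type library. The planned DESeq2 Wald test was not run, a departure from the plan, because count tests were kept for deposited count tables and the files hold none. PARE xrn4 against wild type and its alternatives were not run, because the list holds no abundance or genotype.

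For small RNA size classes the log2 ratio of wild-type to mutant 24-nt share was 3.93, 2.73 over distinct sequences and 3.60 with structural RNA kept. For miRNA sequences rdr2 vs wild type and miRNA sequences dcl2,3,4 vs wild type, 21 (rdr2) and 23 (dcl2,3,4) were called with median-of-ratios size factors and 22 and 22 with library size by listed miRNA reads, against 35 and 36. For annotated loci rdr2 vs wild type and annotated loci dcl2,3,4 vs wild type, 2073 and 1937 were called with TMM factors (1039 and 943 higher), 2059 and 1936 with median-of-ratios size factors, and 2058 and 1968 with reads with 1 genomic position, against 4202 and 4117. With at least 100 reads 2794 loci were called for rdr2 among fewer loci tested. For 24-nt siRNA windows rdr2 vs wild type and 24-nt siRNA windows dcl2,3,4 vs wild type, 329 and 280 were called with TMM factors, 384 and 332 with median-of-ratios size factors, 7449 and 7467 with at least 5 reads, 640 and 640 with at least 100 reads, and 13994 for each with reads counted at every match, where more or fewer windows were tested. Without each mutant replicate in turn, the window count for dcl2,3,4 ranged from 2272 (without dcl2,3,4 replicate 2) to 3483, and the count for annotated loci dcl2,3,4 vs rdr2 from 0 to 3. Where 1 library remained it was assumed to vary like the others. Camera with an estimated correlation called 0 lists against 8, and fry 10: conserved, lineage and DCL4-dependent miRNAs, RNA-directed DNA methylation loci and DCL4-dependent MIR genes in both comparisons with wild type. PARE sites were present in 88.1% with a maximum penalty of 4 and 69.7% with signatures of 1 genomic match, against 81.5%.

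The replicate number was also fitted as a block. Numbers are shared by 2 pairs only and mark a sequencing run by the read names, not by the labels. Deviations of same-numbered libraries correlated at 0.326 (sequences), 0.209 (loci) and -0.0043 (windows). Between the mutants the block called 3 loci (AT3G08845, AT3G08855 and AT5G60120, named after their values were seen) and 4 sequences, against 0. Of the sequences, 2 were listed miRNAs (miR166a and miR157a, each -0.06). From rdr2 to dcl2,3,4, miR166a rose in one run and fell in the other, while miR157a fell in both. The other 2 were unlisted (AGAATCCTGATGATGCTGCAT, which lies inside all 3 loci, and AGACAAAAGCAGACGCAGCTCCA). The block moved no other count by over 1.5 times. Of 92 changes of named features 6 gained a call with the block: miR167a and LHCB1.3 in both comparisons with wild type, AT1G62910 for rdr2 and AT1G63150 for dcl2,3,4. None of these 6 passed with the mutant libraries of both labels summed by run, where GAPC1 gained a call in both comparisons and AT1G63150 lost its call for rdr2.

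The following signs were reversed, but the list is not complete. A scaling shifts all features of a fit alike. For rdr2, library size by listed miRNA reads moved the median locus from -0.95 to -2.25. That shift also makes the smaller changes of LHCB1.3, MIR869A and ACT2 negative. TMM factors moved the median sequence from 1.75 to 0.71, which also makes miR822 rdr2 vs wild type negative. With TMM factors, the log2 changes were miR167a rdr2 vs wild type -0.75, miR167a dcl2,3,4 vs wild type -0.77, miR822 dcl2,3,4 vs wild type -0.91, TAS1A rdr2 vs wild type 0.51, TAS2 rdr2 vs wild type 0.44, AtMU1 rdr2 vs wild type 0.16, TAS1A dcl2,3,4 vs wild type 0.41, TAS2 dcl2,3,4 vs wild type 0.35, AtMU1 dcl2,3,4 vs wild type 0.27, ROS1 dcl2,3,4 vs wild type 0.76 and MIR822A dcl2,3,4 vs wild type 0.91. With median-of-ratios size factors, the log2 changes were miR167a rdr2 vs wild type -1.07, miR822 rdr2 vs wild type -0.97, miR167a dcl2,3,4 vs wild type -1.07, miR822 dcl2,3,4 vs wild type -1.21, TAS1A rdr2 vs wild type 0.49, TAS2 rdr2 vs wild type 0.42, AtMU1 rdr2 vs wild type 0.14, TAS1A dcl2,3,4 vs wild type 0.39, TAS2 dcl2,3,4 vs wild type 0.33, AtMU1 dcl2,3,4 vs wild type 0.25, ROS1 dcl2,3,4 vs wild type 0.74 and MIR822A dcl2,3,4 vs wild type 0.89. With library size by listed miRNA reads, the log2 changes were miR167a rdr2 vs wild type -1.01, miR822 rdr2 vs wild type -0.90, miR167a dcl2,3,4 vs wild type -1.01, miR822 dcl2,3,4 vs wild type -1.16, TAS1C rdr2 vs wild type -0.77, TAS3A rdr2 vs wild type -0.96, TAS3B rdr2 vs wild type -0.47, TAS3C rdr2 vs wild type -0.90, AT1G62910 rdr2 vs wild type -1.12, AT1G63130 rdr2 vs wild type -0.95, AT1G62930 rdr2 vs wild type -0.83, AT1G63150 rdr2 vs wild type -0.97, ROS1 rdr2 vs wild type -1.29, MIR822A rdr2 vs wild type -1.13, RBCS1A rdr2 vs wild type -0.16, EF1A rdr2 vs wild type -0.22, TAS1C dcl2,3,4 vs wild type -0.79, TAS3A dcl2,3,4 vs wild type -1.03, TAS3B dcl2,3,4 vs wild type -0.48, TAS3C dcl2,3,4 vs wild type -0.92, AT1G62910 dcl2,3,4 vs wild type -1.19, AT1G63130 dcl2,3,4 vs wild type -0.94, AT1G62930 dcl2,3,4 vs wild type -0.90, AT1G63150 dcl2,3,4 vs wild type -1.07, RBCS1A dcl2,3,4 vs wild type -0.075 and EF1A dcl2,3,4 vs wild type -0.47. With reads with 1 genomic position, the log2 changes were AT1G62930 rdr2 vs wild type -0.16, AT1G63150 rdr2 vs wild type -0.33, EF1A rdr2 vs wild type -0.030, AT1G62930 dcl2,3,4 vs wild type -0.058 and EF1A dcl2,3,4 vs wild type -0.13. Of 92 changes of named features, 4 lost and 13 gained a call with TMM factors, 10 and 13 with median-of-ratios size factors, 10 and 2 with library size by listed miRNA reads, and 5 and 2 with at least 5 reads. With limma-trend 2 lost and 4 gained a call. Of 89 with the compared libraries only, 3 lost a call, and of 64 with reads with 1 genomic position, 5 did. No named feature was counted as reversed when a replicate was left out, with the block, or under either read filter.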

Other observations

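The tests of the first 2 patterns weighed here were chosen only after their results were seen, and the tests of the codon pattern were written before. The limit on what counts as sampling noise between labels was also set afterwards, as was the restriction of the stop codon profile to fully annotated genes.

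The rise at MIR319a came mainly from 1 sequence, the 23-nt AATGAATGATGCGGTAGACAAAT on the plus strand of chromosome 4, 12353065 to 12353087, inside the annotated MIR319a gene. It had 52 reads in wild type and 16633, 19588, 17849 and 14509 in the mutant libraries, or 52.8 against 10664, 11463, 10866 and 10601 RPM. At MIR839A the 22-nt reads went from 77.2 to 416, 455, 456 and 500 RPM, while exact miR839 (TACCAACCTTTCATCGTTCCC) went from 88.4 to 9.62, 7.61, 4.87 and 5.11 RPM. At the transposon AtMU1, 24-nt reads went from 113 to 8, 13, 8 and 9 and 21-nt reads from 4 to 93, 125, 115 and 88. At AtGP1, 24-nt reads went from 401 to 28, 42, 46 and 40 and 21-nt reads from 67 to 285, 402, 314 and 327. These features were chosen after their values were seen.

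The register of 21-nt siRNAs, counted from the miR173 cleavage position, was kept at TAS1A, while at TAS1C the register 1 nt later gained reads. At TAS1A 89.4% of 21-nt reads lay in register in wild type and 86.0 to 89.7% in the mutant libraries. At TAS1C 45.4% lay in register and 37.6% lay 1 nt later in wild type, against 15.6 to 16.8% and 70.2 to 71.2% in the mutant libraries. In reads unscaled for depth, 1248 lay in register in wild type and 1152, 1208, 1103 and 941 in the mutant libraries. Those 1 nt later went from 1035 to 5072, 5045, 4953 and 4294. Whether they were 1 sequence was not examined. At TAS2 the share in register was 53.0% in wild type and 38.1 to 43.2% in the mutants, and at TAS1B 78.6% and 59.7 to 64.3%.

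The libraries labelled rdr2 and dcl2,3,4 held nearly the same small RNAs. A run effect hiding a difference between the labels is argued against for abundant sequences. Within a run, where the run cannot hide it, the labels differed by a chi-square per degree of freedom of only 1.34 and 2.19. With the run as a block 0.0422% of tested loci and 4 of 19718 sequences differed. That fit had few residual degrees of freedom and its power was not simulated, so its few calls decide little. The same RNA under both labels stays open: libraries of different labels within a run differed by a chi-square per degree of freedom of at most 2.19, above sampling noise but below the 7.67 or more between runs, and no known repeat of 1 library was there to set the noise. Correct labels with a shared phenotype were weighed for each label. For rdr2 they are argued against only if miRNAs themselves were stable, and otherwise stay open. Without RDR2 the 21-nt reads of 24-nt loci should fall to a median log2 change of -1 or lower per listed miRNA read. The lower of the libraries labelled rdr2 had -0.023, with 1396 of 2844 loci higher, which decides neither way. For dcl2,3,4 a correct label is argued against, since TAS loci still held 21-nt siRNAs, which depend on DCL4. In reads unscaled for depth, TAS1A held 2356 in wild type and 2556 and 2361 under this label, with 88.6% and 87.5% in register. Library sizes were 984035 in wild type and 1642633 and 1368615 under this label. TAS1C went from 2750 to 6953 and 6030, TAS2 from 1629 to 1903 and 1545, and TAS3A from 3177 to 6560 and 5419. Reads in register at TAS1C went from 1248 to 1103 and 941. TAS1B went down, from 590 to 390 and 315. Per listed miRNA read, each of these TAS loci was lower than in wild type. The argument thus rests on the presence of these siRNAs, not on an unchanged level. Of single DCL4-dependent small RNAs, miR839 and tasiARF fell under both labels, and miR822 passed the test under neither. The falls of miR839 and tasiARF go with the dcl2,3,4 label, so the argument against it rests on TAS loci alone. Whether another Dicer made the TAS siRNAs was not tested. The 21-nt reads of 7 TAS loci differed between the labels by a median log2 of -0.026 (-0.090 to -0.0051).

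At loci that lost 24-nt reads, 21-nt reads rose in sum. For the pooled reads of 2867 windows, loss of the 24-nt class raising every other share stays open. Their fold change per listed miRNA read had a lower 95% bound of at least 1.96, or 1.47 without the 200 windows with most 21-nt reads. These bounds argue against it only if miRNAs themselves were stable, and they cover resampled loci only. Of listed miRNA reads, miR167a held 90742 of 162247 in wild type and 192135 of 659273 in rdr2 replicate 1. Its log2 change for rdr2 was 0.29, against 2.13 for miR156a and 2.78 for miR158a. The fold change was not computed without miR167a, but would be lower in each mutant library, since miR167a held a larger share of listed miRNA reads in wild type. Loss of the 24-nt class can account for the middle locus of 2844, whose median log2 change on that scale was at most 0.29 from 0. The pooled rise thus rests on a part of the loci. Size selection against longer RNA is argued against, since the ratio of 24-nt to 21-nt reads relative to wild type was at least 0.601 in tRNA fragments and 1.21 to 1.44 in rRNA fragments, against 0.0247 to 0.0274 in non-structural reads, and so are inverted repeats alone, whose median log2 change exceeded that of other loci by at most 0.0475. Processing of the same precursors by another Dicer stays open, as untested. In the libraries labelled rdr2 it would need precursors that RDR2 makes, so there it depends on the label.

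PARE 5' ends repeated every 3 nt in coding sequence, with 35.1% of them at codon position 2 and a signature at 10.8%, 11.6% and 10.6% of codon positions 1, 2 and 3. Base composition is argued against as the whole cause: rates learned in 3' UTRs predicted 33.9% at position 2, so the observed share lay 1.21 points higher. Decay that follows the last ribosome cannot be told apart from other causes here, because the codon signal was present while the density 16 to 17 nt before the stop codon was on average 1.08 times that 30 to 60 nt before it, or 1.15 times with genes of any annotated length: 25.1% of positions 16 nt before it held a signature, the highest of the profile, and 19.9% of those 17 nt before it, against 20.9%. No biological contrast between genotypes was tested, since the signatures are pooled.

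Signatures covered 5.31% of positions in 5' UTRs and 14.6% in 3' UTRs.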
